A study of Rattus norvegicus with 15 samples.

How the data were processed

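The series measured RNA of the posterior cerebral artery of Sprague Dawley rats on 15 Affymetrix Rat230A arrays. The arrays fall into 5 groups of 3: intact animals, sham surgery after 24 h and after 3 d, and 3-vessel occlusion (3VO) after 24 h and after 3 d. Per the labels, each array held RNA pooled from 8 rats. The labels also speak of repeated hybridisation, which leaves open how far the 3 pools of a group are separate animals, so every p-value measures the spread between these arrays. No array number or pool pairs the groups, and no block was used.

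The deposited values are a linear array signal, an intensity that the authors made in GCOS and scaled to a global target on each array. The version of GCOS is not given in the sources used here. The design text gives a target of 500, whereas the mean after trimming 2% at each end was 5000 on each of the 15 arrays, 10 times the stated target. The fixed pseudocount and signal minimum were therefore looser on this scale than planned. The number of arrays, 3 per group, limits the precision.

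The authors' scaling was kept. Signals were taken as log2(signal + 16), and probe sets with a signal of 100 or more on at least 3 arrays were tested, which kept 15737 of the 15923 probe sets. The 57 control probe sets were left out. Gene symbols came from the platform table, updated through Entrez and RefSeq identifiers. A single gene was assigned to 12783 probe sets, several genes to 312 and none to 2771. No genome build was named for the probe sets, so no coordinates are given.

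Groups were compared with limma 3.58.1 in R 4.3.3. lmFit fitted 5 group means to all 15 arrays, with 10 residual degrees of freedom, and eBayes with a variance trend added 4.83 prior degrees of freedom. All tests were 2-sided. The contrasts were 3VO against sham at 24 h and at 3 d, the difference between those effects, and each of the 4 operated groups against intact arteries. Probe sets passed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast. A log2 difference is the difference of group means of log2(signal + 16), with the standard error (SE) of limma. Levels are means of the linear signal with the SD over 3 arrays, and folds are 2 to the power of the log2 difference.

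For the re-analysis, 17 gene lists and 14 marker lists of cell types were drawn up. The gene lists were protease inhibitors, proteases, extracellular matrix, contractile smooth muscle, endothelial cells, adhesion molecules with chemokines and cytokines, growth factors, shear stress and immediate early genes, cell cycle, acute phase, interferon response, hypoxia and glycolysis, heat shock, mitochondrial respiratory chain, glucocorticoid response, cholesterol synthesis and vascular tone. The marker lists covered macrophages, neutrophils, lymphocytes, platelets, erythroid cells, pericytes, leptomeningeal fibroblasts, choroid plexus, neurons, astrocytes, oligodendrocytes, pituitary, peripheral nerve and skeletal muscle. Each list was tested with camera at a preset correlation of 0.01 on the brightest probe set of each of 10360 genes, with adjustment over the 31 lists. The test was repeated with a correlation estimated from the residuals and with fry. Genes past the threshold were counted over all probe sets and again adjusted over the list alone.

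Named genes followed a rule. For 3VO against sham, up to 12 higher and 12 lower genes with the largest log2 difference were taken among those that passed with no overlap between arrays. Where fewer than 10 probe sets passed, the 8 higher and 8 lower non-overlapping genes with the smallest unadjusted p were added as values that did not pass. Against intact arteries the limit was 6 in each direction. In each list up to 4 members with the smallest p were named, and 15 genes were to be given whatever their values, where they could be measured. Contrasts, lists, the naming rule, thresholds and the first set of alternative settings were fixed before the data were examined.

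That first set held pseudocounts of 1 and 64, no signal filter, a minimum of 300, quantile normalization, median centring, a fit without the variance trend, array weights, a single probe set per gene, the array number as a covariate, the operated groups alone, the groups of the contrast alone, and leaving out each array in turn. Alternatives added after seeing the data were a minimum of 1000 with a pseudocount of 160, the mean of the neuron list as a covariate, the means of the neuron and choroid plexus lists as covariates, and a fit without the 2 arrays rich in choroid plexus markers. The tests were also tried on simulated data of 15737 probe sets with 200 changed in each of 5 runs. Changes of 1, 1.5, 2 and 3 on the log2 scale were called in 41.6%, 57.2%, 67.2% and 84.8% of cases, with a mean of 6.2 false calls. The simulated noise was independent between probe sets. With few probe sets past the test, the adjustment asks for a smaller unadjusted p than with 200 changed. These shares are therefore not the power of the real contrasts and may overstate it. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.

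The treatment text of the sham array at 3 d replicate 1 describes the occlusion, whereas its title, source, description and extract say sham, and it was kept as sham. Single-array scans and probe-level data were not used here.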

Results

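Gene expression was measured in the posterior cerebral artery, the vessel that carries collateral flow to the forebrain when other supply arteries are closed. In 3-vessel occlusion (3VO) both vertebral arteries and the left common carotid artery are closed, which lowers blood flow to the brain without an infarct. Arteries were taken 24 h or 3 d after 3VO or after sham surgery, and from intact rats, with 3 arrays in each of the 5 groups and RNA of 8 rats pooled for each array. Signals had a trimmed mean of 5000 on every array, medians between 2559.4 and 2940.9, and between 1.33% and 5.19% of values below 100. The sham array at 3 d whose treatment text describes the occlusion had a Timp1 signal of 15920, against 17320 and 16330 on the other sham arrays at 3 d and 45060 to 67170 after 3VO. Its A2m (17710) and Cp (13680) were the highest of the sham arrays at 3 d, below 20780 and 17480, the lowest after 3VO. Its Acta2 (34190) lay within the 3VO range of 32730 to 46470, with 73660 and 57510 on the other sham arrays. These values do not settle the conflict in the labels.

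The first comparison asked which genes of the artery respond to the occlusion after 24 h, beyond the response to surgery. Timp1, a secreted inhibitor of matrix metalloproteinases, rose from 17400 ± 1090 after sham surgery to 106000 ± 32000 after 3VO (SD, n = 3 arrays each), a 5.87-fold difference (log2 2.55, SE 0.25, limma adjusted p = 0.00069). The broad protease inhibitor A2m rose 3.21-fold, from 8940 ± 1070 to 28700 ± 2320 (log2 1.68, adjusted p = 0.0105). Complement component C3 rose from 6880 ± 1600 to 18800 ± 3740 (log2 1.46, adjusted p = 0.0141). Lcn2, an iron-sequestering acute phase protein, rose from 2170 ± 346 to 14700 ± 7290 (log2 2.63, adjusted p = 0.0141), and Cp, the copper-carrying ferroxidase ceruloplasmin, from 11900 ± 1460 to 46100 ± 3450 (log2 1.96, adjusted p = 0.0191). Pla1a, a phospholipase that acts on phosphatidylserine, rose from 5460 ± 1050 to 18900 ± 3740 (log2 1.79, adjusted p = 0.00908). Lilrb4, an inhibitory receptor of myeloid cells, rose from 346 ± 159 to 4160 ± 1550 (log2 3.57, adjusted p = 0.0191). The eighth probe set to pass is annotated to 3 kininogen genes and lies outside the naming rule, so it was singled out after its values were seen. It rose from 289 ± 247 to 19200 ± 8620 (log2 6.23, SE 0.76, adjusted p = 0.00507), with the lowest sham array at 73. The log2 difference was 5.46 with a signal minimum of 1000 and a pseudocount of 160, and lay between 5.53 and 6.88 when a single array was left out, so the size of the rise is loosely fixed. Kininogens are precursors of bradykinin and inhibitors of cysteine proteases. The probe set specific to Kng2l1 stood at 550 ± 144 after 3VO and 473 ± 416 after sham surgery (log2 0.62) and did not pass. A further pair of Cp probe sets differed by 1.07 (adjusted p = 0.511) and 0.74 (adjusted p = 0.548) on the log2 scale.

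Protease inhibitors are a list the study singled out on these arrays, so their direction is not independent evidence. Of 26 measured members 15 were higher after 3VO at 24 h, with a median log2 difference of 0.06 and a mean of 0.33. The list passed camera (adjusted p = 0.0329), with an adjusted p = 0.439 with an estimated correlation. Timp1 and A2m passed over all probe sets, and 3 members passed when adjusted over the list alone, the third being the neuronal serpin Serpini1 (log2 1.51). Serpina3n (log2 0.14) and the cysteine protease inhibitor Cst3, at 151000 ± 12300 against 149000 ± 10600, did not pass. Acute phase genes rose as a list of 25 (median log2 0.37, adjusted p = 4.31e-05, and adjusted p = 0.379 with an estimated correlation). Of these, 2 passed over all probe sets and 6 when adjusted over the list alone, among them Lcn2, C3, the metal-binding Mt2A (log2 1.36) and the complement protease C1s (log2 0.79).

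Contractile smooth muscle genes were lower after 3VO at 24 h in 24 of 25 cases, with a median log2 difference of -0.57 (adjusted p = 8.72e-12, and adjusted p = 0.379 with an estimated correlation). None of the 25 passed over all probe sets, and 8 passed when adjusted over the list alone. Among these, the myosin light chain Myl9 stood at 40800 ± 12300 after 3VO and 90100 ± 6220 after sham surgery (log2 -1.19). The calcium store protein Casq2 stood at 3290 ± 476 against 6650 ± 1340. The actin cross-linker Flna differed by -0.91 and phospholamban, Pln, by -1.28. Smooth muscle actin, Acta2, stood at 39300 ± 16700 against 76700 ± 11600 (log2 -1.04, adjusted p = 0.505). The contractile list also passed camera as higher after sham surgery at 24 h than in intact arteries, and did not pass for 3VO against intact at 24 h. Its mean per array was 0.286 to 0.494 on sham arrays of 24 h, -0.433 to 0.072 on 3VO arrays of 24 h and -0.562 to 0.292 on intact arrays. The difference is thus relative to sham arrays that stood above the intact ones as a group. Extracellular matrix genes were lower in 38 of 48 cases (median -0.28, adjusted p = 2.74e-05, and adjusted p = 0.388 with an estimated correlation). The basement membrane protein Nid2 differed by -0.80 and the collagens Col5a1 and Col14a1 by -0.62 and -0.61. The matrix cytokine Spp1 ran the other way at 25000 ± 12300 against 6930 ± 243 (log2 1.71) and was the member that passed when adjusted over the list alone. Pericyte markers (11 genes, median -0.30, adjusted p = 0.00842, and adjusted p = 0.379 with an estimated correlation) included the proteoglycan Cspg4 (-0.79), Mcam (-0.93) and the receptor Pdgfrb (-0.58). Endothelial genes were lower in 24 of 29 cases (median -0.25, adjusted p = 0.026, and adjusted p = 0.559 with an estimated correlation), with the receptor Tie1 at -0.69, the nitric oxide synthase Nos3 at -0.76 and the junction protein Pecam1 at -0.19. Growth factor genes had a median of -0.18 (adjusted p = 0.0319, and adjusted p = 0.379 with an estimated correlation), with Igf1 at -0.51 and Tgfb3 at -1.07. Leptomeningeal markers had a median of -0.23 (adjusted p = 0.0261, and adjusted p = 0.475 with an estimated correlation), led by the anion transporter Slc22a6 at -0.79.

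Macrophage markers were higher after 3VO at 24 h in 25 of 28 cases (median log2 0.21, mean 0.45, adjusted p = 1.02e-07, and adjusted p = 0.379 with an estimated correlation). None passed over all probe sets, and 6 passed when adjusted over the list alone. The lysosomal glycoprotein Gpnmb stood at 29700 ± 12400 against 8450 ± 2410 (log2 1.77), the antibody receptor Fcgr2b at 14300 ± 5830 against 4180 ± 1050 (log2 1.73), and the complement genes C1qb and C1qc differed by 1.01 and 0.87. The lysosomal marker Cd68 differed by 0.20. Cell cycle genes were higher in 35 of 45 cases (median 0.26, adjusted p = 3.47e-05, and adjusted p = 0.379 with an estimated correlation), with the replication genes Mcm7 at 0.60 and Pcna at 0.47 and the proliferation marker Mki67 at 1130 ± 189 against 547 ± 251 (log2 1.12, adjusted p = 0.691). Chaperone genes of the heat shock list were higher in 22 of 31 cases (median 0.17, adjusted p = 0.00229, and adjusted p = 0.379 with an estimated correlation), with Hsp90b1 at 0.39 and Calr at 0.42. Hypoxia and glycolysis genes had a median of 0.13 (adjusted p = 0.0367, and adjusted p = 0.379 with an estimated correlation), with the lactate dehydrogenase Ldha at 0.52 and the haem oxygenase Hmox1 at 1.18. Glucocorticoid response genes had a median of 0.25 (adjusted p = 0.0495, and adjusted p = 0.388 with an estimated correlation), with Cdo1 at 1.05 and Fkbp5 at 0.48.

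Markers of brain cells moved with the same comparison. Neuronal markers were higher after 3VO at 24 h in 31 of 32 cases (median log2 0.78, adjusted p = 2.94e-10, and adjusted p = 0.379 with an estimated correlation), with the synaptic Snap25 at 48600 ± 21700 against 20100 ± 5340 (log2 1.19) and the GABA synthesis enzyme Gad1 at 1.88. Astrocyte markers were higher in 16 of 18 cases (median 0.48, adjusted p = 1e-04, and adjusted p = 0.379 with an estimated correlation), with Fabp7 at 1.16 and Gfap at 0.46. Erythroid markers were lower in all 8 cases (median -0.43, adjusted p = 0.00778, and adjusted p = 0.379 with an estimated correlation), with the haem synthesis enzyme Alas2 at -0.75 and the globin Hbb at -0.40. The myelin gene Mbp differed by 0.12 and the oligodendrocyte list by a median of 0.32 (adjusted p = 0.176). With the mean of the neuron list as a covariate all 8 probe sets stayed past the threshold, and the count became 20 (19 higher and 1 lower). With the same covariate 9 lists passed in place of 16. Of the lists whose call ended, the mean went from -0.22 to 0.00 (95% interval -0.24 to 0.24) for extracellular matrix, from -0.21 to 0.06 (-0.22 to 0.34) for leptomeningeal markers, from 0.49 to 0.13 (-0.40 to 0.67) for astrocytes and from -0.15 to -0.05 (-0.24 to 0.13) for growth factors. It went from -0.51 to -0.38 (-0.92 to 0.16) for erythroid, from -0.32 to -0.15 (-0.64 to 0.34) for pericyte, from -0.21 to -0.14 (-0.64 to 0.36) for endothelial and from 0.14 to 0.11 (0.01 to 0.21) for hypoxia genes. These moves were smaller than their SE, so the loss of these 4 calls does not show that brain tissue accounts for them. Without the covariate, intervals already included no difference for matrix (-0.53 to 0.09), leptomeningeal (-0.58 to 0.16), astrocyte (-0.09 to 1.08) and growth factor genes (-0.33 to 0.03). The same held for pericyte (-0.75 to 0.11) and endothelial genes (-0.61 to 0.20), but not for erythroid (-0.96 to -0.06) or hypoxia genes (0.05 to 0.23). Contractile genes still passed with a mean that shrank from -0.60 to -0.35 (-1.01 to 0.31), cell cycle genes at 0.33 before and after (-0.06 to 0.71) and glucocorticoid genes at 0.15 and then 0.17 (-0.20 to 0.54). Macrophage (0.45, then 0.74), acute phase (0.45, then 0.62), protease inhibitor (0.33, then 0.46) and heat shock genes (0.13, then 0.25) also still passed, as did the protease and interferon response lists, which had not passed before. Calls of 7 of the 16 lists also ended in some fits that leave out a single array, and glucocorticoid genes passed in 6 of 15 such fits, endothelial genes and protease inhibitors in 11.

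The other lists did not pass at 24 h. Medians were 0.07 for proteases, 0.00 for adhesion molecules and cytokines, 0.05 for shear stress genes, -0.03 for interferon response, 0.11 for cholesterol synthesis and -0.16 for vascular tone. The median of the mitochondrial list was -0.01 while its test pointed up. Among marker lists, medians were 0.66 for neutrophils, -0.07 for lymphocytes, -0.18 for platelets, -0.23 for choroid plexus, -0.11 for pituitary and 0.29 for peripheral nerve. Skeletal muscle markers had a median of 0.10, a mean of -0.06 and a test that pointed down. Adjusted p values of these lists lay between 0.176 and 0.77. Of single genes in them, the chemokine gene Ccl2 differed by 1.14, the adhesion gene Icam1 by 0.14 and the flow-responsive transcription factor Egr1 by -0.18, and none of these passed.

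Further genes at 24 h had arrays that did not overlap but did not pass, with adjusted p between 0.103 and 0.151. Higher were Glra2, a glycine receptor subunit with a sham mean below 100, Mt2A (log2 1.36), the membrane protein Ifitm1 (1.08), the fatty acid binding protein Fabp5 (0.89), LOC102549726 (0.62) and the polyamine acetylase Sat1 (0.54). Lower were the small GTPase Rrad (-2.82), Wdr35 (-1.97), the actin-associated Synpo2l (-1.48), Wtip (-1.24), Ccdc66 (-1.17), Mast3 (-0.85), the nitric oxide receptor subunit Gucy1a1 (-0.82) and Ehd1 (-0.68). In all, 8 of 15737 probe sets passed in limma, all higher after 3VO, and 1097 had an unadjusted p under 0.05 where chance gives 787. The groups did not overlap for 2426 probe sets, or 15.4%, where chance gives 10%. The count of 8 fell to 1 without 3VO replicate 2 of 24 h, to 5, 2 and 2 without sham replicate 1, 2 or 3 of 24 h, rose to 13 (9 higher and 4 lower) without intact replicate 1, and was 2 without the variance trend. It was 25 with array weights (19 higher and 6 lower), 19 with the array number as a covariate (11 and 8), 24 with neuron and choroid plexus covariates (23 and 1) and 20 with the groups of the contrast alone (10 and 10). The direction was thus not one-sided under these settings.

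**Figure D1:**
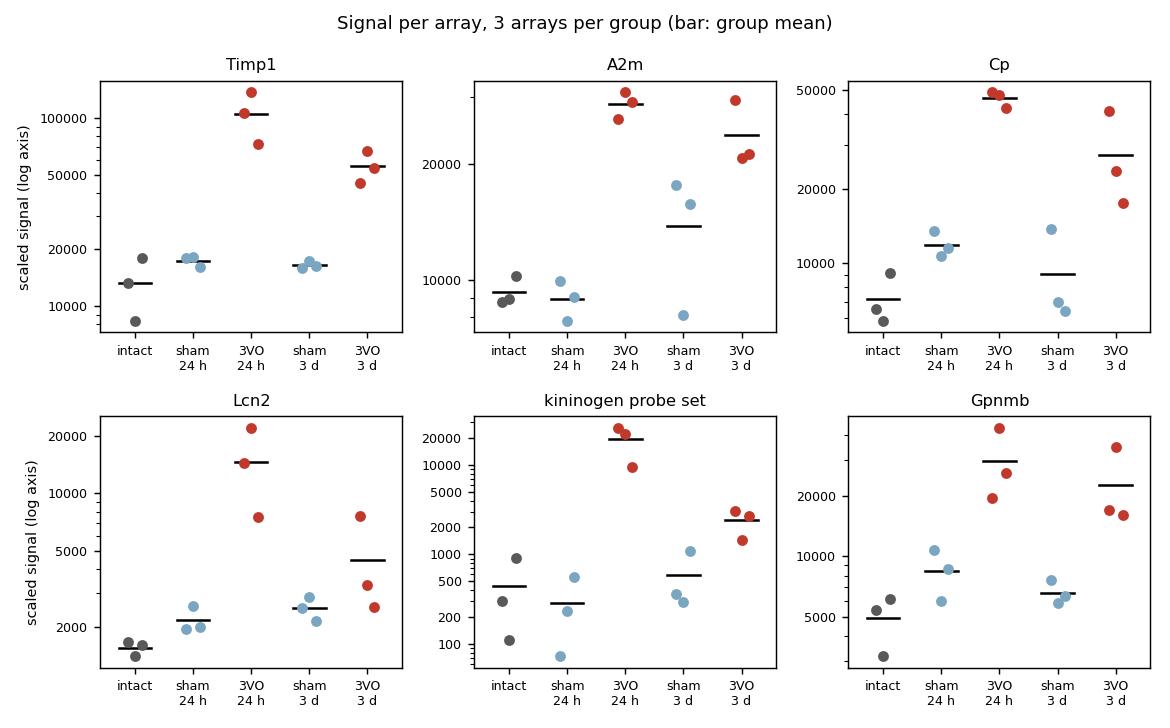
Scaled signal on a log axis for Timp1, A2m, Cp, Lcn2, the kininogen probe set and Gpnmb, with a point for each of the 3 arrays of every group and a bar at the group mean. Timp1 lay between 72980 and 136800 on the 3VO arrays of 24 h, above its 15920 to 18180 on the sham arrays of both times.

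At 3 d the question was which differences between 3VO and sham surgery last. Timp1 stood at 55400 ± 11100 after 3VO and 16500 ± 720 after sham surgery (SD, n = 3 arrays each), a log2 difference of 1.73 (SE 0.25) that did not pass (limma adjusted p = 0.0869). Ccl2, which draws in monocytes, stood at 5620 ± 3310 against 841 ± 615 (log2 2.83, adjusted p = 0.524). The macrophage genes Gpnmb (log2 1.69), Fcgr2b (1.56) and Cd68, at 7690 ± 1130 against 4190 ± 870 (0.89), did not pass either. Mki67 stood at 1710 ± 376 against 567 ± 300 (log2 1.70, adjusted p = 0.756).

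Macrophage markers were higher after 3VO at 3 d in 28 of 28 cases (median log2 0.31, adjusted p = 2.93e-11, and adjusted p = 0.431 with an estimated correlation), and 7 of them passed when adjusted over the list alone, against 0 over all probe sets. Cell cycle genes were higher in 39 of 45 cases (median 0.34, adjusted p = 8.63e-10, and adjusted p = 0.14 with an estimated correlation). The mitotic genes Kif22 (1.07), Cks2 (1.34), Cdk1 (1.39) and Mki67 were the 4 that passed when adjusted over the list alone, against 0 over all probe sets. Proteases had a median of 0.18 (adjusted p = 0.0229, and adjusted p = 0.612 with an estimated correlation), with Htra1 at 0.65 and Mmp8, a collagenase of neutrophils, at -2.31. Contractile smooth muscle genes were lower in 22 of 25 cases (median -0.35, adjusted p = 0.000222, and adjusted p = 0.741 with an estimated correlation), with Flna at -0.57, the myosin Myh11 at -0.55 and Acta2 at -0.36. Endothelial genes were lower in 24 of 29 cases (median -0.21, adjusted p = 0.0126, and adjusted p = 0.741 with an estimated correlation), with Pecam1 at -0.99. Genes of the mitochondrial respiratory chain were lower in 35 of 42 cases (median -0.10, adjusted p = 0.00187, and adjusted p = 0.741 with an estimated correlation), with Ndufs3 at -0.35.

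Erythroid markers at 3 d had a median of -0.66 (adjusted p = 0.000222, and adjusted p = 0.14 with an estimated correlation), and Alas2 (-0.86), Hba-a3 (-0.71), Hbb (-0.61) and Ahsp (-2.33) passed when adjusted over the list alone. Neuronal markers had a median of 0.31 (adjusted p = 0.0229, and adjusted p = 0.836 with an estimated correlation), with Snap25 at 0.36 and a list mean between 0.016 and 0.659 when a single array was left out, while Gfap differed by 0.11 and Mbp by -0.36. Protease inhibitors, chosen by the study on these arrays and so not independent evidence, did not pass as a list at 3 d (median 0.04, adjusted p = 0.267). Timp1 and A2m (0.84) were their 2 members that passed when adjusted over the list alone, while Serpina3n differed by -0.12, Cst3 by 0.01 and Kng2l1 by 0.43. Pituitary markers had a median of -0.18, a mean of 0.31 and a test that pointed up without passing (adjusted p = 0.49).

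Of genes without overlap at 3 d, Cp (1.59), Pla1a (1.28), Ifitm1 (1.02) and the matrix protein Matn2 (0.93) were higher. Lower were the potassium channel partner Kcnip1 and Mast4, both with a 3VO mean below 100, the orexin receptor Hcrtr1 (-1.79), Sptb (-1.53), the flow-sensing polycystin Pkd1 (-1.52), the ephrin Efna1 (-1.30), Rbm38 (-0.62) and the sterol regulator Insig1 (-0.56), all with adjusted p between 0.424 and 0.703. Icam1 (0.25) and Egr1 (-0.07) also did not pass. None of 15737 probe sets passed in limma, 745 had an unadjusted p under 0.05 where chance gives 787, and 1430, or 9.09%, did not overlap where chance gives 10%. With the neuron covariate 7 probe sets passed, Timp1 (1.85), Gpnmb (1.93), Fcgr2b (1.74), Pla1a (1.42), Ifitm1 (1.14), Matn2 (1.04) and Cd68 (1.03), which is a choice made after the data were seen. The count was 1 without 3VO replicate 3 of 24 h, intact replicate 2 or intact replicate 3, and 2 with the array number as a covariate.

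**Figure D2:**
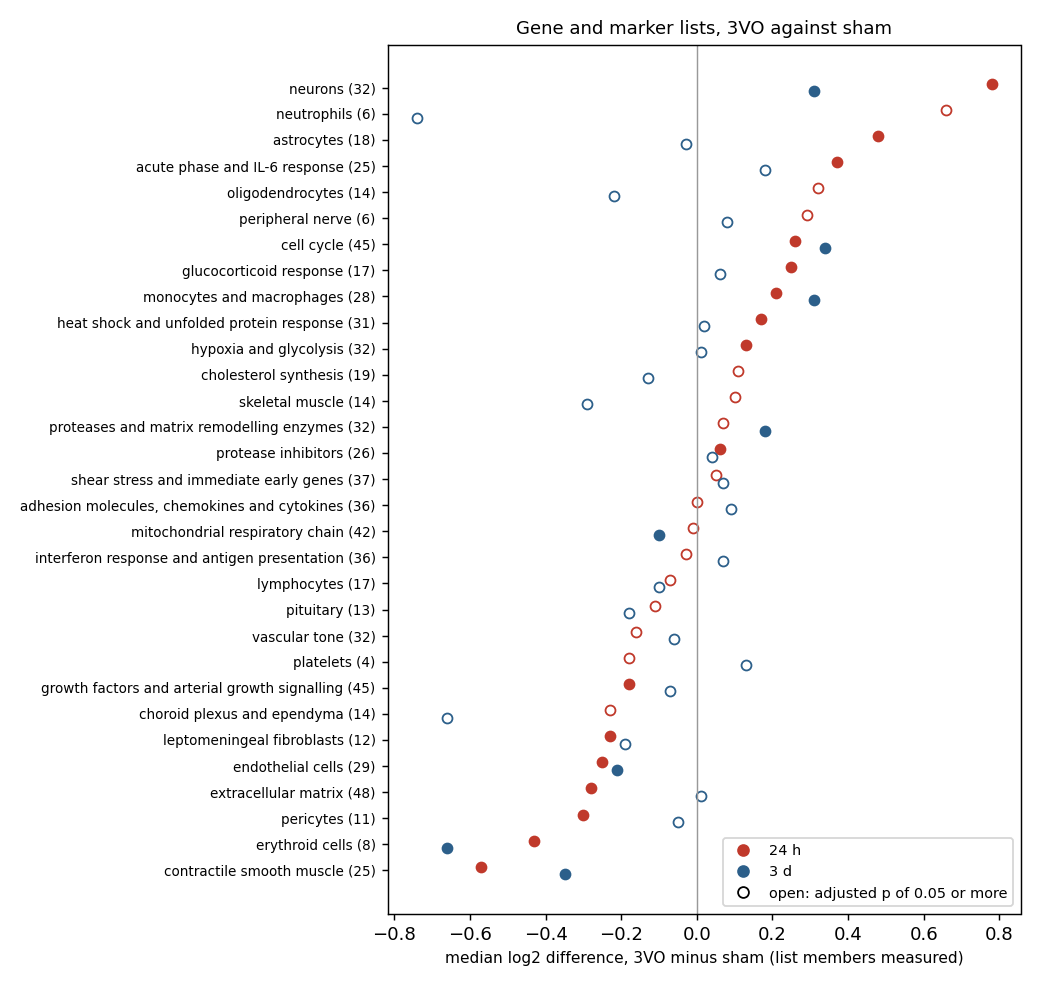
Median log2 difference of 3VO minus sham over the measured members of each of 31 lists, with red points for 24 h, blue points for 3 d and open points where the camera adjusted p was 0.05 or more. Macrophage markers lay at 0.21 and 0.31, and contractile smooth muscle genes at -0.57 and -0.35.

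The difference between the effects at 3 d and 24 h asks whether the response to 3VO changes with time. C3, which had the smallest p and was singled out after its values were seen, was 18800 ± 3740 after 3VO at 24 h and 6680 ± 1100 at 3 d, with sham levels of 6880 ± 1600 and 7810 ± 1230 (log2 difference of effects -1.68). The difference of effects was -4.06 for the kininogen probe set, -2.36 for Lilrb4, -1.95 for Lcn2, -0.84 for A2m and -0.83 for Timp1, which were picked for passing at 24 h, and a smaller effect at 3 d follows in part from that choice. It was 1.69 for Ccl2 and 0.69 for Cd68. None of these differences passed. Extracellular matrix genes (median 0.29, adjusted p = 6.87e-05) and contractile smooth muscle genes (0.22, adjusted p = 0.00438) had a higher effect at 3 d. Neuronal (-0.49, adjusted p = 0.00241), astrocyte (-0.57, adjusted p = 0.00241), neutrophil (-1.20, adjusted p = 0.0162), heat shock (-0.14, adjusted p = 0.0332) and mitochondrial genes (-0.09, adjusted p = 0.0135) had a lower effect at 3 d. Each of these 7 lists had an adjusted p = 0.757 with an estimated correlation. When a single array was left out, the list means lay between 0.196 and 0.42 for matrix, 0.109 and 0.478 for smooth muscle and -0.803 and -0.16 for neuronal genes. They lay between -0.723 and -0.263 for astrocyte, -1.778 and -0.666 for neutrophil, -0.157 and -0.068 for heat shock and -0.157 and -0.04 for mitochondrial genes. Of the 7 calls, 6 ended in some of these fits. With the neuron covariate the matrix (mean 0.32, then 0.18, 95% interval -0.12 to 0.48), smooth muscle (0.29, then 0.13, -0.69 to 0.95), neutrophil (-1.21, then -1.09, -3.12 to 0.94) and astrocyte calls (-0.51, then -0.28, -0.95 to 0.39) ended, and the number of lists was 1 without sham replicate 3 of 24 h, 3 without sham replicate 1 of 3 d and 4 without 3VO replicate 3 of 24 h. No probe set passed in limma (smallest adjusted p = 0.704), and 438 had an unadjusted p under 0.05 where chance gives 787. Of the 8 probe sets past the threshold at 24 h, 7 were higher after 3VO at 3 d, 5 of them with no overlap. Of the 1097 probe sets with an unadjusted p under 0.05 at 24 h, 816, or 74.4%, had the same sign at 3 d. Over all probe sets the effects at the 2 times had a Pearson r of 0.18 and a Spearman rho of 0.22. Pearson r was 0.31 for those with a mean signal over 1000. Probe sets are not independent, and neuronal and erythroid markers moved the same way at both times. The 74.4% therefore does not by itself show a lasting response to 3VO.

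Sham surgery was set against intact arteries to ask what surgery alone does. The intact arrays carry array numbers 13 to 15 and all operated arrays numbers 1 to 12. Any effect linked to that number cannot be told apart from surgery in the contrasts against intact arteries. The array number as a covariate was fitted only to the operated groups. At 24 h the collagen gene Col1a1 stood at 71900 ± 9680 after sham surgery and 38700 ± 4920 in intact arteries (SD, n = 3 arrays each, log2 0.89, limma adjusted p = 0.116). The growth factor Fgf7 stood at 1270 ± 205 against 257 ± 127 (log2 2.37) and the hypoxia-inducible factor Epas1 at 8260 ± 1270 against 3590 ± 192 (log2 1.19). The transcription factor Jund was at 130 ± 30.3 against 1930 ± 598 (log2 -3.71) and the neuronal microtubule protein Mapt at 4720 ± 1260 against 11900 ± 3410 (log2 -1.32). None of these passed, nor did St3gal1 (1.23), Arsb (1.24), Icoslg (1.14), RT1-S3 (1.36), Entpd1 (1.57), Serpini1 (-2.47), Hcrtr2 (-2.77), Kcnc2 (-2.61), Ywhah (-0.92), Lin7a, with a sham mean below 100, or Madd (-1.39). Extracellular matrix genes were higher in 46 of 48 cases (median 0.55, adjusted p = 1.28e-12, and adjusted p = 0.266 with an estimated correlation), with 23 past the threshold when adjusted over the list alone and 0 over all probe sets. Interferon response genes were higher in 36 of 36 cases (median 0.52, adjusted p = 4.55e-11, and adjusted p = 0.328 with an estimated correlation), with the peptide transporter Tap1 at 3490 ± 281 against 1370 ± 393. Macrophage markers had a median of 0.45 (adjusted p = 1.12e-06, and adjusted p = 0.362 with an estimated correlation). Neuronal markers were lower in 31 of 32 cases (median -1.08, adjusted p = 5.28e-13, and adjusted p = 0.328 with an estimated correlation), with Snap25 at 20100 ± 5340 against 77400 ± 44000, and choroid plexus markers had a median of -1.61 (adjusted p = 0.00243, and adjusted p = 0.403 with an estimated correlation). Other cell types were higher as well, with medians of 0.73 for erythroid (adjusted p = 0.000723, and adjusted p = 0.181 with an estimated correlation), 0.49 for leptomeningeal (adjusted p = 0.00141, and adjusted p = 0.362 with an estimated correlation), 0.45 for endothelial (adjusted p = 4.03e-05, and adjusted p = 0.362 with an estimated correlation) and 0.36 for pericyte markers (adjusted p = 0.0469, and adjusted p = 0.397 with an estimated correlation). Markers of blood and meninges thus moved with the matrix, interferon and macrophage lists. What part these tissues have in the differences was not tested. The choroid plexus call ended without intact replicate 2, and the list mean lay between -2.309 and -0.597 over the fits that leave out an array. With the neuron covariate 6 lists passed in place of 17. The macrophage (mean 0.50, then 0.09, 95% interval -0.26 to 0.44) and interferon calls (0.59, then 0.19, -0.18 to 0.55) ended. So did the leptomeningeal (0.46, then 0.07, -0.25 to 0.38) and pericyte calls (0.29, then 0.05, -0.52 to 0.61), while erythroid markers still passed (0.87, then 0.68, 0.06 to 1.30). With neuron and choroid plexus covariates 3 lists passed, and the matrix call ended as well (0.50, then 0.18, -0.13 to 0.49).

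At 3 d after sham surgery, the coagulation factor F13a1 stood at 7650 ± 1430 against 3240 ± 438 in intact arteries (SD, n = 3 arrays each, log2 1.23, limma adjusted p = 0.118). The transcription factor Stat3 stood at 11500 ± 2090 against 5000 ± 1300 (log2 1.22) and Col1a1 at 68900 ± 6670 against 38700 ± 4920 (log2 0.83). The vesicle fusion protein Nsf was at 4410 ± 1190 against 18100 ± 8000 (log2 -1.94) and Jund at 281 ± 192 (log2 -2.85). None passed, nor did Dag1 (0.93), Gnai2 (0.99), Clca1, below 100 on 2 intact arrays, Tmem42 (1.60), Anpep (0.65), Acbd3 (1.09), Ywhah (-0.93), Timm29 (-0.77), Inpp4b (-2.28), Pex6 (-2.77), Tcea2 (-1.87) or Nufip1 (-0.72). Extracellular matrix genes were higher in 47 of 48 cases (median 0.50, adjusted p = 6.63e-11, and adjusted p = 0.359 with an estimated correlation), with 16 past the threshold when adjusted over the list alone and 0 over all probe sets. Interferon response genes were higher in 35 of 36 cases (median 0.39, adjusted p = 1.01e-05, and adjusted p = 0.484 with an estimated correlation). Neuronal markers were lower in 30 of 32 cases (median -1.06, adjusted p = 3.3e-11, and adjusted p = 0.456 with an estimated correlation). Erythroid (median 0.56, adjusted p = 0.0118, and adjusted p = 0.359 with an estimated correlation), leptomeningeal (0.39, adjusted p = 0.0204, and adjusted p = 0.533 with an estimated correlation), endothelial (0.36, adjusted p = 0.000305, and adjusted p = 0.484 with an estimated correlation) and pericyte markers (0.48, adjusted p = 0.0204, and adjusted p = 0.484 with an estimated correlation) were higher as well. Here too markers of blood and meninges moved with the matrix and interferon lists. With the neuron covariate, and with neuron and choroid plexus covariates, 4 lists passed in place of 11. The matrix list still passed, but its mean more than halved, from 0.51 to 0.24 under each (95% intervals -0.01 to 0.50 and -0.03 to 0.52). The interferon call ended under each (0.44, then 0.11 and 0.09, 95% interval with both -0.23 to 0.41). With the neuron covariate the erythroid (0.68, then 0.53, -0.04 to 1.10), leptomeningeal (0.35, then 0.03, -0.26 to 0.32) and pericyte calls (0.38, then 0.18, -0.34 to 0.70) ended. No probe set passed in limma at either time after sham surgery, while 2364 at 24 h and 2236 at 3 d had an unadjusted p under 0.05 where chance gives 787. Without intact replicate 3 the counts were 818 at 24 h and 184 at 3 d. Without 3VO replicate 3 of 3 d, 3 passed at 24 h, and without 3VO replicate 2 of 24 h, 1 passed at 3 d. Without the 2 arrays rich in choroid plexus markers 1 passed at each time, and the groups of the contrast alone gave 2 at 24 h.

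**Figure D3:**
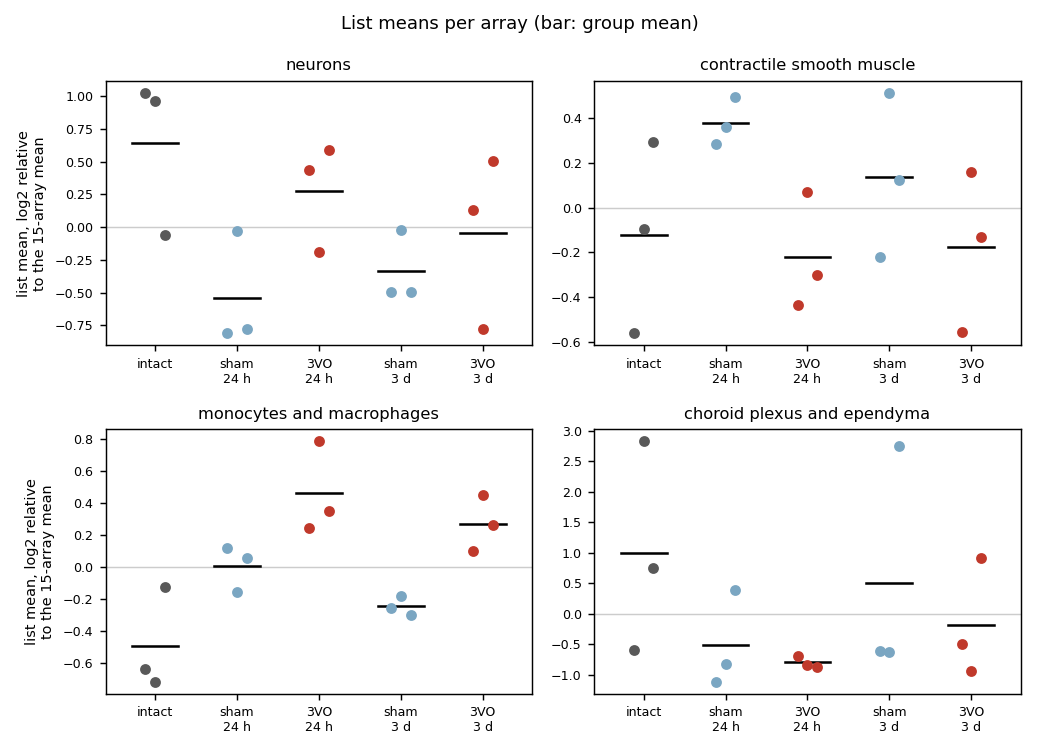
Mean log2 signal of the neuron, contractile smooth muscle, macrophage and choroid plexus lists on each array relative to the mean of the 15 arrays, with a point per array and a bar at the mean of each group of 3. The neuron mean was 1.025 and 0.962 on intact replicates 1 and 2 and -0.061 on intact replicate 3, and the choroid plexus mean was 2.829 on intact replicate 2 and 2.755 on sham replicate 3 of 3 d.

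Arteries after 3VO were also set against intact arteries, which gives the joint response to surgery and occlusion, together with any effect linked to the array number. At 24 h Timp1 rose from 13200 ± 4850 to 106000 ± 32000 (SD, n = 3 arrays each, log2 3.02, limma adjusted p = 7.29e-05) and Lcn2 from 1550 ± 137 to 14700 ± 7290 (log2 3.10, adjusted p = 0.00257). Gpnmb rose from 4910 ± 1540 to 29700 ± 12400 (log2 2.56, adjusted p = 0.00446) and Fcgr2b from 2430 ± 887 to 14300 ± 5830 (log2 2.54, adjusted p = 0.00446). Mki67 rose from 165 ± 86.1 to 1130 ± 189 (log2 2.75, adjusted p = 0.0433) and Lilrb4 by 2.90 on the log2 scale. With a signal minimum of 1000 and a pseudocount of 160 together, the Mki67 difference was 2.01 and did not pass. The reader of methylated RNA Ythdf2 was the single gene that fell, from 9750 ± 4080 to 1740 ± 241 (log2 -2.40, adjusted p = 0.0433). The sham arrays of 24 h were low as well, at 1651 to 3664. Across all groups Ythdf2 was 1551 to 5896 on arrays numbered 1 to 9 and 6188 to 14210 on those numbered 10 to 15. It thus followed the array number, and the fall cannot be credited to 3VO. Macrophage markers were higher in 28 of 28 cases (median 0.77, adjusted p = 6.2e-22, and adjusted p = 0.0878 with an estimated correlation), with 4 past the threshold over all probe sets and 23 when adjusted over the list alone. Acute phase genes had a median of 0.66 (adjusted p = 1.91e-09, and adjusted p = 0.0878 with an estimated correlation), with 5 past the threshold over all probe sets and 9 when adjusted over the list alone, among them Lbp (2.25) and C1s (1.23). Cell cycle genes had a median of 0.39 (adjusted p = 5.14e-08, and adjusted p = 0.0979 with an estimated correlation), and neuronal markers of -0.41 (adjusted p = 0.00839, and adjusted p = 0.638 with an estimated correlation). The neuronal call ended without 3VO replicate 2 of 24 h, intact replicate 1 or intact replicate 2, with a list mean between -0.715 and -0.129. In all, 28 probe sets were higher and 1 lower. This count of 29 was 15, 7 and 17 without 3VO replicate 1, 2 or 3 of 24 h, 15, 14 and 227 without intact replicate 1, 2 or 3, 19 without sham replicate 3 of 24 h and 19 without sham replicate 2 of 3 d. It was 8 without the variance trend, 15 with median centring, 14 with neuron and choroid plexus covariates, 9 without the 2 arrays rich in choroid plexus markers and 3 with the groups of the contrast alone.

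At 3 d after 3VO, Ccl2 rose from 428 ± 123 in intact arteries to 5620 ± 3310 (SD, n = 3 arrays each, log2 3.49, limma adjusted p = 0.0321) and Mki67 from 165 ± 86.1 to 1710 ± 376 (log2 3.33, adjusted p = 0.0277). Timp1 rose to 55400 ± 11100 (log2 2.12, adjusted p = 0.00659) and Gpnmb to 22700 ± 10600 (log2 2.16, adjusted p = 0.0317). The endothelial tip cell gene Esm1 rose from 1320 ± 353 to 6120 ± 3090 (log2 2.07, adjusted p = 0.0459) and the magnesium transporter gene Nipal1 to 523 ± 215 (adjusted p = 0.0467). All 3 intact arrays lay below 100 for Nipal1, so its fold depends on the pseudocount, and its call ended with a pseudocount of 64. The ethanolamine kinase gene Etnk1 fell from 21500 ± 629 to 14700 ± 1240 (log2 -0.56, adjusted p = 0.0349). On the sham arrays of both times Etnk1 stood at 16420 to 18360 and Nipal1 at 103 to 773.9. Every sham array thus differed from the intact arrays in the same direction, and neither difference was particular to 3VO. Adhesion and chemokine genes rose as a list of 36 (median 0.39, adjusted p = 0.00058), and of all calls in the 7 contrasts this was the single call to hold with an estimated correlation (adjusted p = 0.0464). Camera at the preset correlation also called this list higher for sham against intact at both times. When a single array was left out, its mean was 0.264 to 0.399 for sham at 24 h and 0.347 to 0.46 for sham at 3 d. For 3VO at 3 d it was 0.504 to 0.617. The list was not called for 3VO against sham at either time, so the rise is not particular to the occlusion. Extracellular matrix genes were higher in 44 of 48 cases (median 0.57, adjusted p = 2.16e-12, and adjusted p = 0.195 with an estimated correlation), with 26 past the threshold when adjusted over the list alone and 0 over all probe sets. Cell cycle genes had a median of 0.60 (adjusted p = 8.58e-10, and adjusted p = 0.11 with an estimated correlation), macrophage markers of 0.66 (adjusted p = 2.16e-12, and adjusted p = 0.195 with an estimated correlation) and mitochondrial genes of -0.26 (adjusted p = 1.68e-11, and adjusted p = 0.195 with an estimated correlation). Neuronal markers had a median of -0.56 (adjusted p = 4.94e-07, and adjusted p = 0.466 with an estimated correlation), with a list mean between -1.038 and -0.32 when a single array was left out. At both times 11 probe sets were higher than in intact arteries, of Timp1, A2m, Gpnmb, Cp, Pla1a, Fcgr2b, Tpm3, Ifitm1, Mki67, C1s and Crispld2, where 0.059 would be shared if the calls were independent. They are not, since both contrasts use the same 3 intact arrays. An unadjusted p under 0.05 in both contrasts was found for 735 probe sets. In 20 simulations of unchanged groups, with shared intact arrays that were simulated too, the mean was 168. The simulated arrays lacked the uneven neuron and choroid plexus content of the real intact arrays. The single contrasts had 1567 such probe sets at 24 h and 2032 at 3 d, where chance gives 787. Setting 735 against 168 therefore cannot show how much of the overlap the shared arrays produce. Part of the overlap may come from the shared arrays. In all, 33 probe sets were higher and 2 lower at 3 d. This count of 35 was 13, 0 and 7 without 3VO replicate 1, 2 or 3 of 3 d, 5, 4 and 258 without intact replicate 1, 2 or 3, 23, 5 and 6 without sham replicate 1, 2 or 3 of 24 h, and 21 without 3VO replicate 1 of 24 h. It was 4 without the variance trend, 2 with median centring, 4 with the neuron covariate, 4 with neuron and choroid plexus covariates, 22 with a single probe set per gene, 7 without the 2 arrays rich in choroid plexus markers and 0 with the groups of the contrast alone.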

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

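Of the tests below, the comparison of smooth muscle with endothelial genes was chosen only after the result was seen, and the neuron covariate was added after the data were seen. The results in this part are those whose 3VO effect differed between 24 h and 3 d by the test of the difference itself, or whose arrays moved in opposite ways at the 2 times.

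The median effect of 3VO was higher at 3 d than at 24 h for extracellular matrix genes (0.29) and contractile smooth muscle genes (0.22). It was lower at 3 d for heat shock genes (-0.14), mitochondrial respiratory chain genes (-0.09), neutrophil markers (-1.20), neuronal markers (-0.49) and astrocyte markers (-0.57). Each passed camera at the preset correlation, and each had an adjusted p = 0.757 with an estimated correlation. Ccdc66 was lower on every 3VO array than on every sham array at 24 h and higher on every 3VO array at 3 d, with a difference of effects of 1.65 that limma did not call (adjusted p = 0.704).

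The smooth muscle pattern at 24 h was weighed further, since contractile genes were lower after 3VO while neuronal markers were higher. The list mean differed by -0.60 (95% interval -1.19 to -0.01), and with the neuron mean as a covariate by -0.35 (-1.01 to 0.31), where camera at the preset correlation still called the list. That interval over arrays holds both 0 and the whole difference, so brain tissue carried over with the 3VO arteries could account for any part of it, and this explanation cannot be told apart from a lower expression in the wall. A smaller share of vessel wall in the 3VO pools might lower smooth muscle and endothelial genes alike, and the difference between their effects was -0.40 (-1.12 to 0.33), too wide to settle it. A change of the smooth muscle cells after 3VO also stays open. The list was also called higher after sham surgery at 24 h than in intact arteries, with a mean of 0.283 to 0.71 when a single array was left out. It was not called for 3VO against intact at 24 h. A level raised on the sham arrays therefore cannot be told apart from one lowered on the 3VO arrays.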

How the results depend on the processing

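The neuron and choroid plexus covariates, the minimum of 1000 with a pseudocount of 160, and the fit without the 2 arrays rich in choroid plexus markers were chosen after seeing the data. Counts of probe sets stayed within 1.5 times of those reported under both pseudocounts, no filter, both signal minima and quantile normalization. The operated groups alone were fitted only for the difference of effects, with 0 probe sets in either case. Of 3406 values of named genes under alternatives, 3104 kept direction and side of the threshold, 180 were weaker, 88 stronger and 34 reversed, and 0 of those reversed had passed. Most of these results had not passed to begin with and had no call to lose. All 180 weaker values belong to results that had passed, so 3104 of 3406 is not the share of calls that held. Of 1961 values of lists that had passed, 1551 stayed, 404 were weaker and 6 had a test that pointed the other way. Where a value moved, the cause was not tested, except that groups of the contrast alone hold fewer arrays.

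Median centring gave 15 (24 h 3VO against intact) and 2 (3 d 3VO against intact) probe sets, and Cst3 0.00 at 24 h. Without the variance trend, 2 passed for 3VO against sham at 24 h, and 8 and 4 for 3VO against intact at 24 h and 3 d. Array weights gave 25 at 24 h and Cst3 -0.034 at 3 d. A single probe set per gene gave 22 for 3 d 3VO against intact. The array number as a covariate gave 19 at 24 h, 2 at 3 d, Cst3 -0.022 and Mbp -0.02 at 24 h.

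The neuron covariate gave 20 and 7 probe sets for 3VO against sham at 24 h and 3 d, and 4 for 3 d 3VO against intact. Cst3 was -0.003 and Mbp -0.078 at 24 h. Lists past the test numbered 9 at 24 h, 4 for the difference of effects, 6 and 4 for sham against intact at 24 h and 3 d. The mean of the leptomeningeal list turned to 0.06 at 24 h. For 3 d sham against intact it shrank to 0.028 and only the direction of its test turned. With both covariates 24, 7, 14 and 4 probe sets passed (3VO against sham, then against intact, at 24 h and 3 d). Cst3 was -0.012 at 24 h and -0.01 at 3 d, Mbp -0.16 at 24 h, and at 3 d Serpina3n 0.008, Gfap -0.027 and Snap25 -0.034. Lists numbered 9 and 13 for 3VO against sham, 4 for the difference, 3 and 4 for sham against intact, and 8 and 8 for 3VO against intact. The leptomeningeal mean was 0.051 at 24 h. The leptomeningeal (3 d sham against intact, mean 0.023), macrophage (24 h sham against intact, 0.061) and interferon lists (3 d sham against intact, 0.09) kept a positive mean while their tests turned. The neuron and choroid plexus lists have no value where their own mean is the covariate.

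Without the 2 arrays rich in choroid plexus markers, 1 probe set passed for sham against intact at each time, 9 and 7 passed for 3VO against intact at 24 h and 3 d, lists numbered 7 for 3 d sham against intact, and Cst3 was -0.077 and Gfap -0.123 at 3 d. Groups of the contrast alone gave 20 (24 h), 1 (3 d), 2 (24 h sham against intact), and 3 and 0 for 3VO against intact. With an estimated correlation, 0 lists passed in each contrast but 3 d 3VO against intact, with 1. Directional fry called 0 lists for 3VO against sham at both times and for the difference, and 4, 4 and 5 where its count moved against intact arteries. Mixed fry, which asks for change either way, called 5 (24 h), 1 (3 d), 0 (difference) and 5 (3 d sham against intact).

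Leaving out each array in turn gave 1 to 13 probe sets at 24 h, 0 to 1 at 3 d, 0 to 818 and 0 to 184 for sham against intact at 24 h and 3 d, and 7 to 227 and 0 to 258 for 3VO against intact. The lowest count at 24 h came without 3VO replicate 2 and the highest counts against intact without intact replicate 3. Without that array only intact replicates 1 and 2 remain, with neuron means of 1.025 and 0.962. Lists ranged from 1 to 8 for the difference of effects (1 without sham replicate 3 of 24 h, 3 without sham replicate 1 of 3 d, 4 without 3VO replicate 3 of 24 h), 7 to 15 for 3 d sham against intact and 8 to 18 for 24 h 3VO against intact (both lowest without intact replicate 2). At 24 h Cst3 ranged from -0.036 to 0.086, Pecam1 from -0.50 to 0.11, Mbp from -0.16 to 0.43, Serpina3n from -0.067 to 0.30, Icam1 from -0.048 to 0.30 and Kng2l1 from -0.15 to 1.32. At 3 d Cst3 ranged from -0.077 to 0.12, Gfap from -0.12 to 0.36, Egr1 from -0.26 to 0.086, Serpina3n from -0.27 to 0.02 and Snap25 from -0.017 to 0.745. Timp1 passed at 24 h in all 15 of these fits, the kininogen probe set in 14, A2m and Pla1a in 12, C3 in 11, Lcn2 in 10, and Cp and Lilrb4 in 9.

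Of the lists called for 3VO against sham at 24 h, 9 passed in all 15 fits that leave out an array. Without the arrays in brackets, where replicates are of 24 h, the call ended for protease inhibitors (3VO 2, sham 2 and 3, intact 1), endothelial genes (3VO 1 and 2, sham 1 and 2), growth factors (3VO 3, sham 1), hypoxia genes (3VO 1 and 3, sham 2), erythroid markers (3VO 3, sham 2) and leptomeningeal markers (3VO 3, sham 1 and 3). Glucocorticoid genes passed in 6 of 15. At 3 d, macrophage, cell cycle and erythroid lists passed in all 15. The call ended, with replicates of 3 d, for proteases (3VO 2 and 3, sham 1 and 2), contractile genes (3VO 1, sham 2), endothelial genes (3VO 2 and 3, sham 1), mitochondrial genes (3VO 1, sham 3) and neuronal markers (3VO 1 and 3, sham 1 and 3). Of the lists the report gives against intact arteries, choroid plexus markers for sham at 24 h passed in 14 of 15 fits (lost without intact 2) and neuronal markers for 3VO at 24 h in 12 (lost without 3VO 2, intact 1 and intact 2). Pericyte markers passed in 7 for sham at 24 h and in 13 at 3 d (lost without sham 1 and intact 1), with list means of 0.082 to 0.452 and 0.174 to 0.544. For sham at 3 d leptomeningeal markers passed in 12 (lost without sham 1, intact 1 and intact 2) and erythroid markers in 14 (lost without intact 2). Adhesion and chemokine genes passed in 13 for sham at 3 d (lost without sham 1 and intact 2). The others passed in all 15. Over these fits the list mean for 3VO against sham ranged widely for macrophage (0.289 to 0.559), pericyte (-0.40 to -0.213), glucocorticoid (0.095 to 0.232), endothelial (-0.32 to -0.092), growth factor (-0.191 to -0.08) and leptomeningeal genes (-0.286 to -0.088) at 24 h, and for proteases (0.113 to 0.293), contractile (-0.493 to -0.124), endothelial (-0.438 to -0.145) and mitochondrial genes (-0.156 to -0.039) at 3 d.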

Other observations

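In this part, the tests of residual blood, of choroid plexus tissue and of a difference across the whole array were chosen only after the result was seen, and the neuron covariate was added after the data were seen.

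The rise of Timp1 at 24 h had no parallel in its measured relatives. The matrix metalloproteinase inhibitor Timp2 differed by -0.08 and 0.11 on its 2 probe sets after 3VO at 24 h, and Timp3 by -0.07, -0.17, -0.31 and -0.24 on its 4, with limma adjusted p of 0.789 or more. Genes of vascular tone went both ways at 24 h, with 11 of 32 higher. The G protein regulator Rgs2 stood at 12300 ± 1310 after 3VO against 7990 ± 503 after sham surgery (SD, n = 3 arrays each, log2 0.62) and the peptide receptor Vipr2 at 2130 ± 587 against 725 ± 200 (log2 1.53). Gucy1a1 was at 9840 ± 762 against 17400 ± 2000 (log2 -0.82). These 3 passed when adjusted over the list alone and 0 passed over all probe sets. Among inflammatory genes at 24 h, the cytokine Tnf was at 160 ± 191 against 794 ± 204 and the chemokine Cxcl10 at 1300 ± 177 against 2580 ± 526 (log2 -0.98), and both passed when adjusted over the list alone but not over all probe sets (adjusted p = 0.312 and 0.264). The inducible nitric oxide synthase Nos2 differed by -2.46 at 24 h (adjusted p = 0.505) and by 2.72 at 3 d (adjusted p = 0.703).

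Hormone genes of the pituitary and hypothalamus were high on single arrays. Growth hormone, Gh1, stood at 24600 on 3VO replicate 2 of 3 d and 10100 on sham replicate 2 of 24 h, and prolactin, Prl, at 2920 and 3870 on the same arrays. Vasopressin, Avp, stood at 46200 on sham replicate 1 of 24 h and at 12600 and 15100 on intact replicates 1 and 2, and oxytocin, Oxt, at 18600 on that sham array.

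Macrophage genes were higher after 3VO at 24 h, by 0.45 in the list mean (95% interval 0.05 to 0.85, and 0.289 to 0.559 when a single array was left out). If microglia in carried-over brain tissue were the whole cause, the neuron covariate would remove the difference, but with it the difference was 0.74 (0.43 to 1.04). Leukocytes of residual blood would bring red cells with them, yet the erythroid list mean differed by -0.51 (-0.96 to -0.06). With the neuron covariate the erythroid difference was -0.38 (-0.92 to 0.16), an interval that includes no difference. The erythroid call also ended without 3VO replicate 3 or sham replicate 2 of 24 h. Residual blood is therefore not excluded. More macrophages, or more active ones, in or around the artery after 3VO may account for the pattern. Microglia activated in that tissue stay open, as does blood rich in leukocytes.

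Choroid plexus genes were highest on intact replicate 2 and on sham replicate 3 of 3 d, with list means of 2.829 and 2.755. The list mean was also raised on 3VO replicate 3 of 3 d (0.908), intact replicate 3 (0.756) and sham replicate 3 of 24 h (0.391). It lay between -1.119 and -0.499 on the rest. The fit without the 2 highest arrays thus does not remove all of this signal. On intact replicate 2 and sham replicate 3 of 3 d, Ttr stood at 282000 and 261000, against at most 189000 on the other arrays, and Folr1 at 28400 and 27600. Of 14 measured choroid plexus markers, 12 had their 2 highest values on these arrays, which is the pattern itself and no test of its cause. Of 7 measured genes of choroid plexus epithelium outside the list, 4 (Mfrp, Calml4, Krt18 and Tmem72) also had their 2 highest values there, against 3.76% of other genes, while Slc13a4, Krt8 and Ecrg4 did not. Choroid plexus tissue in both pools is a candidate explanation. The arrays were scaled to the same trimmed mean, so a difference of the whole array could remain only at some signal levels. The 50 probe sets nearest in level to each marker argue against it, with a median log2 offset from the other 13 arrays of 0.005 and 0.075, against 3.73 and 3.62 for the markers. Sham replicate 3 of 3 d did differ among dim probe sets, with a 5th percentile of 200 against 96 to 145 on the other arrays. Skeletal muscle markers were also highest on the same 2 arrays, with list means of 1.657 and 0.571. Other tissue in these pools was not tested. No biological explanation was tested.

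Other splits of the same arrays were counted for each contrast. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For 3VO against sham at 24 h the real split called 8 probe sets and the highest of the others 0, so 1 split reached the real count. For 3VO against intact the counts were 29 against 0 at 24 h and 35 against 1 at 3 d. Where limma called 0, every split reaches the real count by construction, so these counts say nothing about chance. This holds for 3VO against sham at 3 d and for sham against intact at each time (10 of 10 splits, highest other count 1, 2 and 2) and for the difference of effects (100 of the 100 drawn from 200 possible splits, highest other count 1).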
